A study of Mus musculus with 8 samples.

How the data were processed

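Synovial cells of mouse ankle and wrist joints were profiled by single-cell RNA sequencing in 4 droplet libraries holding 17 hashtagged animals. Per the labels' protocols, sorted cells were stained with TotalSeq-B hashtag antibodies, animals were pooled, up to 25,000 cells were hyper-loaded into a well, and libraries of 3' transcript ends and of hashtags were made with 10x Genomics chemistry of version 3.1. Hyper-loading gives many droplets with cells of more than 1 animal. Hashtags 1 to 3 marked arthritic animals and hashtag 4 the healthy animal in 3 libraries, and hashtags 1 to 5 marked arthritic animals in the FAP-sorted library, per the labels.

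The deposited matrices held raw counts of unique molecular identifiers (UMIs) for 32285 genes and the hashtags of each barcode, with no normalization by the authors. They were made with Cell Ranger 6.0.0 for the 3 unsorted libraries and 5.0.0 for the FAP-sorted library, per the file headers, while the submitters' processing notes name version 6.0.6 and genome build mm10 for all. A deposited per-cell annotation gave the library, hashtag, genotype, treatment and 1 of 7 classes for 24227 of the 47658 barcodes. How the authors filtered cells, called hashtags and made the classes is not given in the sources used here. The annotation also held UMI, gene and hashtag counts per cell as the authors computed them, a deposited mitochondrial fraction of UMIs, and a deposited stress score and cell-cycle scores whose gene sets are not given. Of these, the stress score was used, as a description. The annotation was joined to the matrices by library and barcode. Genotype and treatment matched the label of the hashtag in all 24227 cells, and so did the hashtag totals. UMI totals were equal in 13444 cells (55.5%) and lower in the annotation by at most 41 UMIs in the others.

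Fibroblasts were the 5 fibroblast classes of the annotation, lining, Mmp3+, Il6+, Cd200+ and Pi16+, and the other 2 classes, chondrocytes and osteoblasts, were left out. Animals were the replicates. Raw counts were summed per animal and tested with edgeR 4.0.16 (R 4.3.3; TMM scaling, filterByExpr by group, quasi-likelihood test, Benjamini-Hochberg adjustment, threshold 0.05). The fit held the 12 animals of the unsorted libraries with group as the only term, so that the groups shared 1 estimate of the spread. The FAP-sorted comparison was fitted over 8 animals. Every log2 fold change, SE and adjusted p of a gene comes from these fits unless another is named. Library could not be a term of this fit without resting each treatment effect on 1 healthy animal per library, and that fit was an alternative. Fibroblast depth was 4508588 to 36786390 UMIs per animal. CPM is used for counts-per-million units of the animal's summed cells, with TMM-scaled library sizes.

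Class shares were compared by two-sided exact permutation tests on 1 share per animal. Healthy was set against arthritic within libraries over 64 arrangements, the 3 arthritic groups were compared by an F statistic over all assignments of 9 animals, and FAP-sorted animals were set against untreated ones over 56 splits, each adjusted over classes. A total of 27 gene lists, 18 for fibroblast programmes and 9 for markers of other cells, were tested with camera (limma 3.58.1, preset correlation 0.01). Estimated correlations and fry, which tests whether the genes of a list move 1 way on balance, were alternatives. Of 189 list tests, 20 had a median, mean and test direction of different sign, none of them past the threshold. Overlap and reversal of responses were set beside 20 simulations of unchanged groups against the same control animals.

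Other cells were clustered from all libraries together. Cells outside the annotation were given an animal with HTODemux (Seurat 5.3.0, quantile 0.99) on the hashtag counts. It called 547, 1084, 562 and 680 hashtag doublets in the untreated, TNF-inhibited, IL-17-inhibited and FAP-sorted libraries and left 4023, 2974, 4372 and 3193 barcodes negative. Annotated cells kept the animal of the annotation, which HTODemux shared in 90.3%, 86.2%, 86.7% and 99.0% of them. This gave an animal to 7847, 7559, 9038 and 8038 barcodes. Scrublet (expected rate 0.1, in scanpy 1.11.5) marked 0, 0, 0 and 2 cells at its automatic threshold, which cannot be right for hyper-loaded wells, so 229, 411, 229 and 170 top-scoring cells were removed, as many as doublets of the same animal expected from the hashtag doublets. The score separated hashtag doublets from other cells with areas under the curve of 0.73, 0.62, 0.71 and 0.74, so doublets remain. Cells with at least 500 genes and at most 10% mitochondrial UMIs were kept, 7119, 6369, 7842 and 6721. They were log-normalized and clustered on 2000 variable genes, 30 principal components and 15 neighbours by the Leiden method (leidenalg 0.10.2, resolution 0.6) into 19 clusters. A cluster was named where 3 or more fixed markers were detected and its 10 leading genes by fold did not go against the name. Of the named classes, 8 were compared. Fibroblast-like, tenocyte-like and osteoblast-like clusters, which share fibroblast markers, and an unnamed cluster of 268 cells were not compared as classes, a choice made after seeing the data. Animals with under 20 cells of a clustered class were left out of its gene tests. Gene tests within 1 annotated fibroblast class had no such minimum.

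The comparisons, tests, lists, markers, rule for naming genes and most alternatives were fixed before the data were examined. Named were the 8 largest rises and the 8 largest falls among called genes whose groups did not overlap and whose mean was at least 10 CPM, without unnamed gene models and mitochondrial, ribosomal, hemoglobin and sex-linked genes. All members of the matrix-degradation list and the pair Cd200 and Dkk3 were added for fibroblasts, with up to 2 passing members per direction of each other list. The text gives a selection of these, with 195 values of 122 genes. Genes outside the rule, namely those given for comparison with another treatment or cell class, were chosen after their values were seen. For genes with 3 or fewer UMIs in a group, a ratio of CPM over the summed animals was given with an exact binomial interval (95%, scipy 1.17.1), which covers counting error only.

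Alternatives were DESeq2 1.42.0, DESeq2 size factors in edgeR, no low-count filter, a filter of 10 CPM in 3 animals, each animal left out, only the 2 groups compared, a library term, the hashtag number as a replicate block, 413 fibroblasts drawn per animal, a strict hashtag rule (at least 50 counts and 5 times the next hashtag, which 14289 annotated cells passed), own fibroblast-like clusters, the largest fibroblast class alone, Leiden resolution 1.2, and 1000 genes with 5% mitochondrial UMIs. The gene test was tested on simulated data, with counts drawn from the real means and 200 genes changed. For the 12 animals and 14129 genes, edgeR recovered 17.9%, 59.7% and 93.9% of genes changed 1.5-fold, 2-fold and 4-fold and called 6 unchanged genes. For the 8 animals and 13211 genes it recovered 47.8%, 77.6% and 97% and called 13, and for endothelial-like cells and 8094 genes 7.5%, 52.2% and 90.9% and called 12. DESeq2 recovered 32.8%, 68.7% and 93.9% for the 12 animals over 14348 genes and called 20 unchanged genes.

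Coordinates came from a reference annotation of the same build, matched by Ensembl identifier for 32235 of 32285 genes (99.8%). Other tools were Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scikit-learn 1.9.0 and matplotlib 3.10.9. All counting was the authors', and reads shared between near-identical genes, such as the class I genes H2-Q6 and H2-Q7, the pair Bglap and Bglap2 or Saa genes, could not be assigned again.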

Results

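Single-cell RNA was sequenced from the synovium, the membrane that lines joints, of mouse ankles and wrists. The arthritic animals carried a human TNF transgene (hTNFtg197) and had received Il23mc for 9 days, and the healthy animals were untreated wild types. The cells came from 17 animals in 4 droplet libraries, and hashtag antibodies marked the animal of each cell. In 3 libraries of viable CD45-negative cells taken without FAP and Pdpn enrichment, 3 arthritic animals were pooled with 1 healthy animal. The arthritic animals of these libraries were untreated, given an antibody against human TNF (TNF-inhibited) or given an antibody against mouse IL-17A (IL-17-inhibited). The remaining library held viable CD45-negative cells sorted for FAP and Pdpn, surface proteins of activated fibroblasts, from 5 arthritic animals with no inhibitor (FAP-sorted). The files held 11827 barcodes and 149149135 unique molecular identifiers (UMIs) for the untreated library, 10879 and 149863971 for the TNF-inhibited, 13105 and 180057537 for the IL-17-inhibited, and 11847 and 157528632 for the FAP-sorted library. The deposited annotation gave an animal and a class to 24227 of the 47658 barcodes. Fibroblast UMIs per animal were 4508588 to 7307067 in healthy, 12952645 to 33132051 in untreated, 12372684 to 34962428 in TNF-inhibited, 21928368 to 36786390 in IL-17-inhibited and 13695149 to 28874555 in FAP-sorted animals. The healthy animals of the 3 libraries held 749, 541 and 413 annotated fibroblasts, and the healthy hashtag had the highest raw count in 9.9% to 34.8%. Of the 541 and 413, 23.1% and 17.7% had a Y-linked UMI, and 65.4% and 67.3% Xist only. Errors are SD for CPM (counts-per-million) and shares, and SE for log2 fold changes. Coordinates are those of genome build mm10.

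To ask which kinds of fibroblasts healthy, arthritic and treated joints held, the class shares of the deposited annotation were compared. Pi16+ fibroblasts, named for a peptidase inhibitor gene, made up 43.0% ± 1.16 (SD, n = 3) of the fibroblasts of healthy animals and 1.2% ± 0.24 (n = 3) of those of untreated arthritic animals. Mmp3+ fibroblasts, named for the matrix-cleaving protease stromelysin, made up 3.70% ± 1.90 in healthy and 38.8% ± 3.70 in untreated arthritic animals. Il6+ fibroblasts held 37.4% ± 0.831 and 47.8% ± 4.64, Cd200+ fibroblasts 9.33% ± 0.563 and 6.03% ± 1.5, and lining fibroblasts 6.62% ± 1.10 and 6.14% ± 0.48. Within the libraries, the healthy share minus the mean share of the arthritic animals, treated or not, was 41.7 percentage points for Pi16+ and -38.8 for Mmp3+. Both had a two-sided exact permutation p of 0.0156, the smallest that 64 arrangements can give, and an adjusted p of 0.0391 over the 5 classes. The direction was the same in 3 of 3 libraries. The adjusted p was 0.0521 when any 1 arthritic animal of the 3 libraries was left out and 0.156 when any 1 healthy animal was left out, both with fewer arrangements. The class names are genes, and Mmp3, Il6 and Cd200 differed in level between healthy and untreated arthritic fibroblasts.

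The 2 inhibitors left Pi16+ fibroblasts scarce. Their share was 0.216% ± 0.15 (n = 3) in TNF-inhibited and 2.49% ± 1.27 (n = 3) in IL-17-inhibited animals. Mmp3+ fibroblasts held 50.4% ± 8.85 and 38.2% ± 5.42, Il6+ fibroblasts 30.4% ± 7.18 and 35.4% ± 7.13, Cd200+ fibroblasts 10.2% ± 4.06 and 14.4% ± 1.35, and lining fibroblasts 8.88% ± 3.54 and 9.46% ± 4.33. Two-sided exact permutation tests over the 3 arthritic groups gave p = 0.0214 for Pi16+, 0.0429 for Cd200+, 0.0607 for Il6+, 0.139 for Mmp3+ and 0.264 for lining fibroblasts. None passed adjustment, with 0.101 as the lowest adjusted p. Without IL-17-inhibited animal 3, the Pi16+ share passed at an adjusted p of 0.0179. A comparison of 3 animals with 3 cannot give a p below 0.1.

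**Figure D1:**
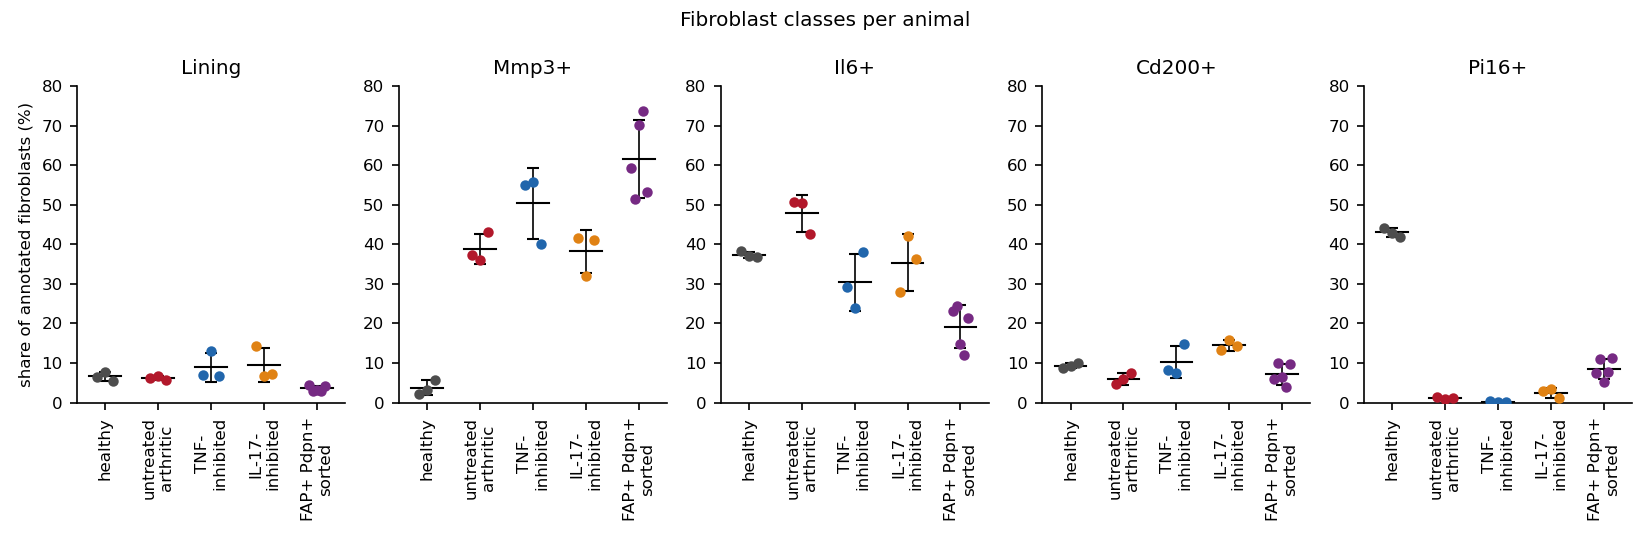
Share of each fibroblast class of the deposited annotation in percent of an animal's fibroblasts (vertical axis) by group (horizontal axis), with a point per animal, a line at the mean and an error bar of 1 SD. Pi16+ fibroblasts hold 43.0% in healthy and 1.2% in untreated arthritic animals, and Mmp3+ fibroblasts 3.70% and 38.8%.

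Next, fibroblast RNA of untreated arthritic and healthy animals was compared, summed over classes whose shares differed. The complement, matrix-degradation and IL-17-response lists were higher in untreated arthritic animals, also with an estimated correlation. Mmp3 (chromosome 9, 7445822 to 7455975) averaged 15200 ± 339 CPM in untreated arthritic and 1110 ± 202 CPM in healthy animals (n = 3 each), a log2 fold change of 3.78 ± 0.21 (adjusted p = 1.1e-07). The acute-phase gene Saa3 (chromosome 7, 46711998 to 46715700) rose by 4.45 ± 0.42 to 42600 ± 4640 CPM, and Lcn2, which encodes an iron-sequestering protein, rose by 3.89 ± 0.30 to 5480 ± 460 CPM. The B-cell attractant Cxcl13 rose by 4.29 ± 0.32, and Tnfsf11, which encodes the osteoclast-forming signal RANKL, by 4.14 ± 0.28. Il4i1, an amino acid oxidase gene, rose by 5.00 ± 0.55, Cybb, a subunit of the phagocyte NADPH oxidase, by 4.81 ± 0.26, and the adhesion molecule gene Chl1 by 4.62 ± 0.16. Fabp7, a fatty acid binding protein gene, and the acute-phase gene Orm1 rose by 4.67 ± 0.71 and 4.66 ± 0.38. Among the genes with the largest falls, Cytl1 fell by 5.34 ± 1.09, the osteocalcin genes Bglap and Bglap2 fell by 4.52 ± 0.20 and 4.30 ± 0.23, and Smpd3, a sphingomyelinase gene, fell by 4.17 ± 0.31. Scg3, Efhd1 and Engase fell by 3.95 ± 0.22, 3.75 ± 0.26 and 3.56 ± 0.29, and the epidermal gene Krtdap fell by 3.56 ± 0.33. Adjusted p lay between 3.2e-09 and 0.0025 for all these genes. The edgeR test called 4116 of 14348 genes, 2070 higher and 2046 lower.

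The fixed lists were tested on the same sums, and how much of the list differences came from the class mix was not measured. Of 12 complement genes, 9 rose and 1 fell, among them Cfb with 3.06 ± 0.15 and the complement brake Cd55 with -1.61 ± 0.23 (camera adjusted p = 9.01e-16, or 0.0168 with an estimated correlation). Adjusted over the list alone, the same numbers of complement genes passed. Of 12 matrix-degradation genes, 9 rose, 1 fell and 2 did not pass (adjusted over the list alone 10 rose and 1 fell; adjusted p = 3.0e-08, or 0.0168 with an estimated correlation). Besides Mmp3, the risen members were Mmp9 (2.75 ± 0.60), Mmp10 (4.06 ± 0.72), Mmp12 (2.91 ± 0.42), Mmp13 (2.72 ± 0.24), Mmp14 (1.01 ± 0.15), Adamts5 (0.90 ± 0.13), the cathepsin gene Ctsk (0.70 ± 0.15) and the protease inhibitor gene Timp1 (1.37 ± 0.18). Plau, which encodes urokinase, fell by 1.07 ± 0.21, while Mmp2 had 0.34 ± 0.13 and Adamts4 -0.01 ± 0.26. Mmp10 rested on 2 UMIs in the healthy animals together, which gave a CPM ratio of 15 with an exact 95% counting interval of 4.08 to 125. Of 20 IL-17-response genes, 9 rose and none fell (13 rose when adjusted over the list alone; adjusted p = 1.13e-08, or 0.0199 with an estimated correlation).

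Of 29 interferon-response genes, 18 rose and 1 fell, with Iigp1 at 3.07 ± 0.41, the chemokine gene Cxcl9 at 2.67 ± 0.59 and Irf1 at -1.19 ± 0.23 (19 rose and 1 fell when adjusted over the list alone; adjusted p = 5.11e-11, or 0.306 with an estimated correlation). Of 22 cytokine and chemokine genes, 11 rose and 1, the eosinophil attractant Ccl11, fell (13 and 1 when adjusted over the list alone; adjusted p = 1.08e-07, or 0.123 with an estimated correlation). Of 23 glycolysis and hypoxia genes, 14 rose, such as the lactate transporter gene Slc16a3 at 2.15 ± 0.44, and 1 fell (16 and 1 when adjusted over the list alone; adjusted p = 4.88e-05, or 0.602 with an estimated correlation). Sublining genes fell in 8 of 15 cases and rose in 2, with Dpp4 at -3.18 ± 0.30, the basement membrane collagen Col15a1 at -2.86 ± 0.20 and the chemokine gene Cxcl12 at 1.71 ± 0.15 (9 fell and 3 rose when adjusted over the list alone; adjusted p = 9.45e-06, or 0.197 with an estimated correlation). Lining genes fell in 7 of 12 cases and rose in 2, with Clic5 at -2.94 ± 0.43, Htra4 at -2.87 ± 0.42 and Thbs4 at 2.24 ± 0.22 (the same numbers when adjusted over the list alone; adjusted p = 0.0213, or 0.602 with an estimated correlation). The pair Cd200 and Dkk3 moved apart, with -0.99 ± 0.31 for the immune-inhibitory surface protein gene Cd200 and 0.56 ± 0.14 for the Wnt modulator gene Dkk3 (both passed alone as well; adjusted p = 0.952). Cd200 did not pass without untreated animal 1 or any 1 healthy animal, with an adjusted p of up to 0.095, and the other 42 named genes of this comparison passed without each animal in turn.

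The remaining programme lists did not pass as groups. They were collagens and fibrous matrix (13 genes rose and 6 fell of 32, adjusted p = 0.0624), cell cycle (2 rose of 19, adjusted p = 0.155), the Notch pathway (1 rose and 3 fell of 10, adjusted p = 0.155), TNF and NF-kB feedback (8 rose and 5 fell of 18, adjusted p = 0.171), and myofibroblast and TGF-beta response (7 rose and 5 fell of 18, adjusted p = 0.346). Others were dissociation and immediate early genes (1 rose and 4 fell of 21, adjusted p = 0.459), the Wnt pathway (3 rose and 6 fell of 18, adjusted p = 0.667), bone remodelling signals (5 rose and 4 fell of 13, adjusted p = 0.701) and checkpoint genes (3 rose and 4 fell of 15, adjusted p = 0.837). Markers of other cells moved as well. Neutrophil genes rose in 2 of 3 cases, with Camp at 3.68 ± 0.23 (3 when adjusted over the list alone; adjusted p = 9.65e-05, or 0.0204 with an estimated correlation). Keratinocyte genes fell in 6 of 7 cases (6 when adjusted over the list alone; adjusted p = 0.00293, or 0.38 with an estimated correlation). Cartilage and bone genes fell in 3 of 10 (3 when adjusted over the list alone; adjusted p = 0.00331, or 0.231 with an estimated correlation). Leukocyte (adjusted p = 0.0501), muscle (0.171), mural (0.346), Schwann (0.346), erythroid (0.459) and endothelial markers (0.837) did not pass as groups. With a library term, which the healthy animals identify, 2317 genes passed, and Slc16a3 (adjusted p = 0.051), Plau (0.066) and Cd200 (0.22) lost their call. Against the healthy animal of the untreated library alone 2259 genes passed, with the spread taken from the other groups. Of all genes, 45.1% had groups that did not overlap, where chance gives 10%.

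**Figure D2:**
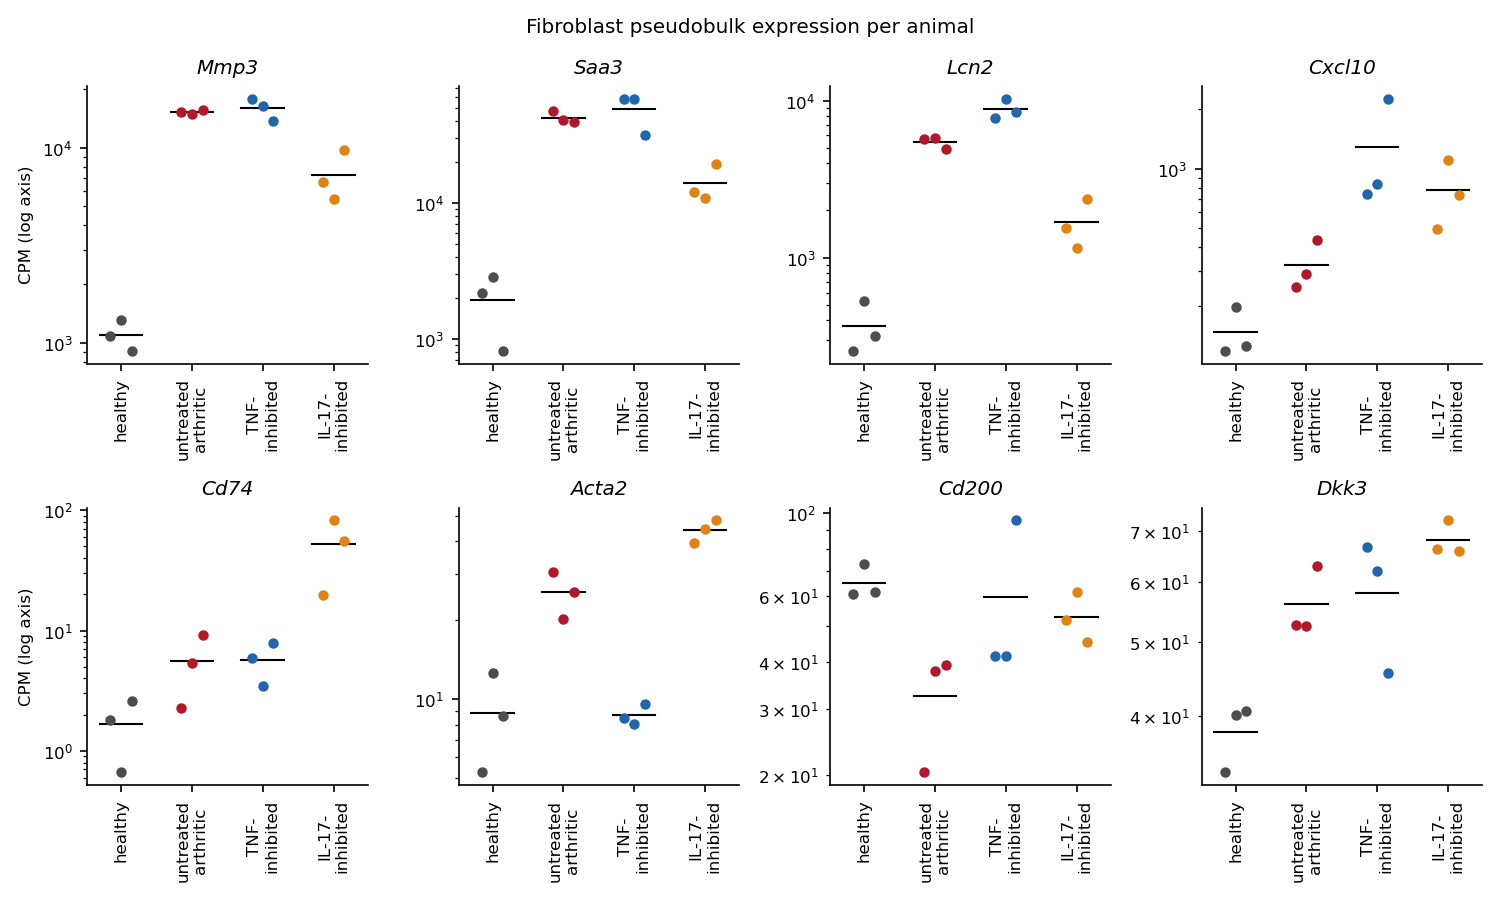
Level of 8 genes in CPM of an animal's fibroblasts (vertical axis, log scale) by group (horizontal axis), with a point per animal and a line at the mean of the 3 animals. Mmp3 averages 1110 CPM in healthy, 15200 in untreated, 16000 in TNF-inhibited and 7250 in IL-17-inhibited animals.

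To ask what TNF inhibition changed in arthritic fibroblasts, TNF-inhibited animals were compared with untreated arthritic animals. The interferon-response list was higher and the myofibroblast and sublining lists lower, though none of the 3 passed with an estimated correlation (adjusted p of 0.193, 0.149 and 0.154). Mmp3, Saa3 and Lcn2 did not pass. Ifit3 (chromosome 19, 34583531 to 34588731), an interferon-induced antiviral gene, rose by 2.41 ± 0.39 to 46.3 ± 13.9 CPM from 8.31 ± 3.11 CPM (n = 3 each, adjusted p = 0.0084), and the antiviral gene Rsad2 rose by 2.26 ± 0.35 (adjusted p = 0.0077). The T-cell attractants Cxcl9 and Cxcl10 rose by 2.10 ± 0.55 and 1.98 ± 0.41, Cd274, which encodes the checkpoint ligand PD-L1, by 1.88 ± 0.43, and Ifit1, Tgtp2 and the metallothionein gene Mt3 by 1.87 ± 0.40, 1.94 ± 0.49 and 2.16 ± 0.50. Spp1, which encodes osteopontin, rose by 1.56 ± 0.18. Acta2 (chromosome 19, 34241090 to 34255590), smooth muscle actin, fell by 1.55 ± 0.20 to 8.71 ± 0.803 CPM, and Thbs1, a matrix glycoprotein gene, fell by 1.42 ± 0.24. Fabp7, the lipase gene Lpl, the Wnt inhibitor Dkk2, Abca8a and the growth factor gene Ptn fell by 2.04 ± 0.48, 1.65 ± 0.27, 1.63 ± 0.32, 1.60 ± 0.32 and 1.48 ± 0.21. Mmp3 had a change of 0.07 ± 0.19 (adjusted p = 0.86), Cd200 of 0.84 ± 0.30 (adjusted p = 0.11) and Dkk3 of 0.06 ± 0.13 (adjusted p = 0.84). The test called 797 of 14348 genes, 363 higher and 434 lower.

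Of the 29 interferon-response genes, 16 rose and none fell (27 rose when adjusted over the list alone; camera adjusted p = 3.68e-22, or 0.193 with an estimated correlation). Of 23 glycolysis and hypoxia genes, 5 rose, such as Ankrd37 at 1.85 ± 0.45 and the oxidoreductase gene Ero1l at 0.88 ± 0.21 (14 when adjusted over the list alone; adjusted p = 7.99e-08, or 0.448 with an estimated correlation). Of 15 sublining genes, 7 fell, such as Col15a1 at -1.15 ± 0.21 and Clec3b at -0.91 ± 0.11 (10 when adjusted over the list alone; adjusted p = 7.99e-08, or 0.154 with an estimated correlation). Of 18 myofibroblast genes, 6 fell, among them Acta2 and the actin-binding protein gene Tagln at -1.33 ± 0.31 (9 fell and 1 rose when adjusted over the list alone; adjusted p = 1.74e-06, or 0.149 with an estimated correlation). Of 32 collagen and matrix genes, 3 fell, among them Thbs1 and Postn at -0.83 ± 0.19 (3 fell and 2 rose when adjusted over the list alone; adjusted p = 0.0212, or 0.486 with an estimated correlation). Of the 12 matrix-degradation genes, Mmp12 rose by 1.40 ± 0.33, Adamts4 fell by 1.09 ± 0.26 and 10 did not pass (4 rose and 1 fell when adjusted over the list alone; adjusted p = 0.572). The Notch pathway had 2 falls of 10, the receptor gene Notch3 at -1.2 ± 0.19 and its target Heyl at -1.95 ± 0.41 (adjusted p = 0.214). No IL-17-response gene of 20 passed (adjusted p = 0.214), nor any cell-cycle gene of 19 (adjusted p = 0.214) or lining gene of 12 (adjusted p = 0.214).

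Markers of other cells moved in the same comparison. Muscle genes fell in 5 of 8 cases, with Ckm at -1.48 ± 0.40 and Myh1 at -1.62 ± 0.31 (8 when adjusted over the list alone; adjusted p = 7.99e-08, or 0.193 with an estimated correlation). Mural genes fell in 2 of 8 (2 when adjusted over the list alone; adjusted p = 0.0264, or 0.193 with an estimated correlation). Keratinocyte genes rose in 2 of 7 cases (5 when adjusted over the list alone; adjusted p = 9.7e-05, or 0.237 with an estimated correlation). Of 2 erythroid genes 1 fell (2 when adjusted over the list alone; adjusted p = 0.000866, or 0.149 with an estimated correlation). In the healthy animals of the untreated, TNF-inhibited and IL-17-inhibited libraries, the 8 muscle genes summed to 341, 140 and 101 CPM and the 7 keratinocyte genes to 26.5, 54.8 and 77.0 CPM. Treatment and library were the same split of the arthritic animals. With a library term, edgeR called 0 genes, with 799 at an unadjusted p under 0.05, while the interferon (adjusted p = 2.88e-11), myofibroblast (2.65e-06), sublining (0.00338) and glycolysis (0.0188) lists still passed. None of the 28 named genes passed with it, and Mt3 (-0.70), Adamts4 (0.17) and Ckm (0.39) changed sign. Within the Il6+ class alone Tagln had a change of 0.26. The count was 105, 146 and 178 without untreated animals 1, 2 and 3, and 170 without TNF-inhibited animal 2. Without each animal in turn, 9 named genes always passed, Ifit3, Rsad2, Spp1, Acta2, Thbs1, Lpl, Ptn, Clec3b and Notch3. The others lost their call without 2 to 6 of the 6 animals, mostly an untreated animal or TNF-inhibited animal 2, with an adjusted p of up to 0.16 for Cxcl9, 0.13 for Ckm and Tgtp2, 0.12 for Adamts4, Ankrd37, Ero1l, Mmp12 and Mt3, 0.11 for Cd274, Fabp7 and Tagln, 0.1 for Heyl and Postn, 0.099 for Cxcl10, 0.095 for Ifit1, 0.078 for Dkk2, 0.075 for Abca8a, 0.073 for Myh1 and 0.055 for Col15a1. The healthy animal of the TNF-inhibited library differed from that of the untreated library in the treatment direction for 83.1% of 587 called genes and 66.6% of 6755 other genes.

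To ask what IL-17 inhibition changed, IL-17-inhibited animals were compared with untreated arthritic animals. IL-17-response genes were lower and interferon-response genes higher as lists, though neither passed with an estimated correlation (adjusted p of 0.154 and 0.291). Mmp3 fell by 1.07 ± 0.19 to 7250 ± 2180 CPM from 15200 ± 339 CPM (n = 3 each, adjusted p = 0.0073). Lcn2 (chromosome 2, 32384633 to 32388252) fell by 1.70 ± 0.27 to 1690 ± 618 CPM (adjusted p = 0.0043). Saa3 fell by 1.59 ± 0.37 to 14200 ± 4490 CPM (adjusted p = 0.023), Cxcl13 by 1.98 ± 0.29 (adjusted p = 0.0026), and Ptgs2, the inducible cyclooxygenase gene, by 1.25 ± 0.30 (adjusted p = 0.025). The formyl peptide receptor gene Fpr2 and the signalling antagonist gene Sostdc1 fell by 2.25 ± 0.37 and 2.01 ± 0.29, and Tnfsf11 fell by 0.94 ± 0.22. Cd74 (chromosome 18, 60803848 to 60812652), the invariant chain of MHC class II, rose by 3.15 ± 0.49 to 52.8 ± 31.7 CPM from 5.62 ± 3.47 CPM (adjusted p = 0.0041). The class II gene H2-Ab1 rose by 2.24 ± 0.38, the class I gene H2-Q6 by 1.86 ± 0.32, Cxcl9 by 2.18 ± 0.55 and the chemokine gene Ccl5 by 1.71 ± 0.49. Acta2 rose by 0.80 ± 0.19 and Tagln by 1.11 ± 0.27. Bglap rose by 2.11 ± 0.19, the histone gene Hist1h2ap by 2.79 ± 0.61, AA467197 by 1.72 ± 0.25 and the epidermal keratin gene Krt14 by 2.07 ± 0.31. Cd200 had a change of 0.69 ± 0.30 (adjusted p = 0.17) and Dkk3 of 0.28 ± 0.13 (adjusted p = 0.2). The test called 1212 of 14348 genes, 545 higher and 667 lower.

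Of the 20 IL-17-response genes, 7 fell and none rose (8 when adjusted over the list alone; camera adjusted p = 0.000319, or 0.154 with an estimated correlation). Of the 29 interferon-response genes, 6 rose, among them Cxcl9 and the class I gene H2-D1 at 1.24 ± 0.15 (11 when adjusted over the list alone; adjusted p = 3.92e-12, or 0.291 with an estimated correlation). Of the 18 myofibroblast genes, 5 rose (6 when adjusted over the list alone; adjusted p = 0.0197, or 0.291 with an estimated correlation). Of 18 TNF and NF-kB feedback genes, 4 rose, such as the adhesion molecule gene Vcam1 at 0.61 ± 0.13 and Traf1 at 0.59 ± 0.16 (8 rose and 2 fell when adjusted over the list alone; adjusted p = 0.021, or 0.525 with an estimated correlation). Of 15 checkpoint and immune-regulatory genes, 3 rose, among them Cd276 at 0.62 ± 0.17 and Tgfb1 at 0.44 ± 0.09 (3 when adjusted over the list alone; adjusted p = 0.028, or 0.291 with an estimated correlation). Of 12 lining genes, Clic5 rose by 1.60 ± 0.41 and 11 did not pass (2 rose when adjusted over the list alone; adjusted p = 0.0236, or 0.525 with an estimated correlation). Of the 12 matrix-degradation genes, Mmp3 and Adamts5 fell, the latter by 0.68 ± 0.13, Mmp9 rose by 1.2 ± 0.30 and 9 did not pass (the same when adjusted over the list alone; adjusted p = 0.189). Of 22 cytokine and chemokine genes, 3 rose and 4 fell (3 and 7 when adjusted over the list alone; adjusted p = 0.071).

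Muscle genes fell in 7 of 8 cases, with Ckm at -2.12 ± 0.40 and Tnnt3, Tnni2, Atp2a1 and Tcap among the largest falls (8 when adjusted over the list alone; adjusted p = 1.13e-12, or 0.154 with an estimated correlation). Keratinocyte genes rose in 5 of 7 cases (7 when adjusted over the list alone; adjusted p = 2.94e-07, or 0.157 with an estimated correlation). Cartilage and bone genes rose in 3 of 10 (3 when adjusted over the list alone; adjusted p = 0.0236, or 0.313 with an estimated correlation). Neutrophil genes fell in 2 of 3 cases (3 when adjusted over the list alone; adjusted p = 0.000194, or 0.078 with an estimated correlation). Of these 3 genes 2 are also IL-17-response genes, 1 of them among the 7 that fell. Erythroid genes fell in 1 of 2 (2 when adjusted over the list alone; adjusted p = 0.00408, or 0.154 with an estimated correlation). With a library term, edgeR called 0 genes, with 1107 at an unadjusted p under 0.05, while the interferon (adjusted p = 1.18e-08), lining (1.18e-08), mural (0.00162, higher), IL-17-response (0.00574), cytokine (0.00574, lower) and checkpoint (0.00574) lists passed. None of the 32 named genes passed with it, and Krt14 (-0.04), Tagln (-0.06), Mmp9 (-0.50), Ccl5 (-0.52), Ckm (0.22) and Atp2a1 (0.38) changed sign. Within the Il6+ class alone Mmp3 had a change of 0.09. The count was 459, 326 and 496 without untreated animals 1, 2 and 3, and 754, 466 and 652 without IL-17-inhibited animals 1, 2 and 3. Without each animal in turn, 18 named genes always passed, among them Mmp3, Lcn2, Cxcl13 and Cd74. The others lost their call without 2 to 6 of the 6 animals of both groups (Hist1h2ap without any 1 untreated animal), with an adjusted p of up to 0.16 for Cd276, 0.15 for Traf1, 0.13 for Ccl5, 0.12 for Clic5 and Cxcl9, 0.11 for Acta2 and Tagln, 0.096 for Mmp9 and Ptgs2, 0.089 for Saa3 and Tnfsf11, 0.079 for Vcam1, 0.073 for Tgfb1 and 0.068 for Hist1h2ap. The healthy animal of the IL-17-inhibited library differed from that of the untreated library in the treatment direction for 76.3% of 858 called genes and 62.9% of 6484 other genes.

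**Figure D3:**
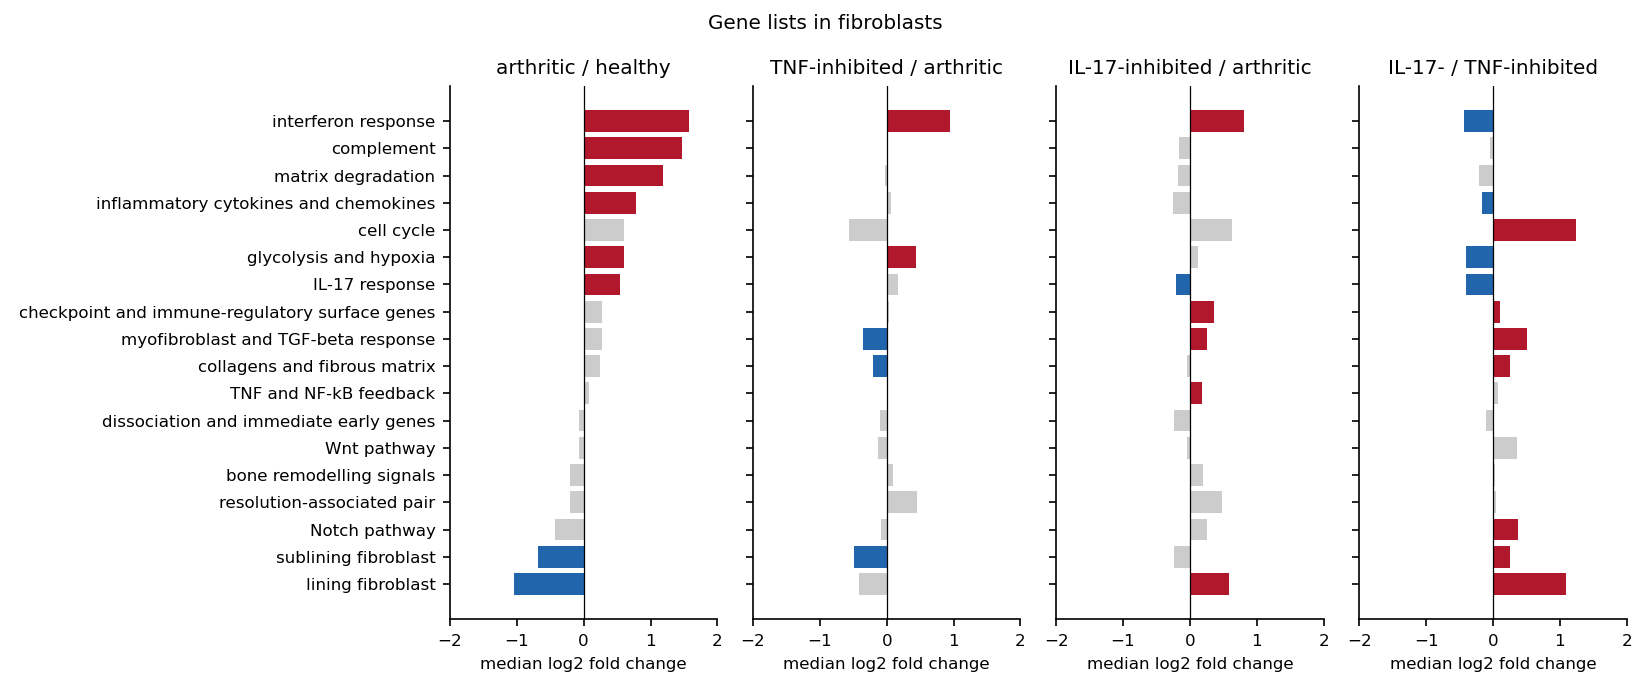
Median log2 fold change of each of 18 fixed gene lists (horizontal bars) in 4 fibroblast comparisons (panels), coloured where the camera adjusted p is under 0.05 and grey elsewhere. Interferon-response genes have medians of 1.58 in arthritic against healthy, 0.95 with TNF inhibition and 0.81 with IL-17 inhibition.

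To compare the 2 inhibitors directly, IL-17-inhibited animals were set against TNF-inhibited animals. The myofibroblast list was higher and the IL-17-response list lower with IL-17 inhibition, also with an estimated correlation. Acta2 was higher by 2.35 ± 0.20, with 44.0 ± 4.41 against 8.71 ± 0.803 CPM (n = 3 each, adjusted p = 0.0002). Tagln was higher by 2.44 ± 0.30 (adjusted p = 0.0007), Cd74 by 3.28 ± 0.51 (adjusted p = 0.0027), the cytokine receptor gene Il2rg by 2.45 ± 0.26 (adjusted p = 0.00028) and the cell-cycle gene Ccnd1 by 2.28 ± 0.28 (adjusted p = 0.0007). Lcn2 was lower by a log2 change of -2.39 ± 0.28, the acute-phase gene Saa2 by -2.44 ± 0.25, Mmp12 by -2.19 ± 0.34, the neutrophil growth factor gene Csf3 by -1.95 ± 0.39, Cxcl13 by -1.75 ± 0.28, Mmp3 by -1.14 ± 0.19 and Ctla2a by -2.79 ± 0.60. Of 18 myofibroblast genes, 9 were higher, among them the matrix receptor gene Lrrc15 at 2.37 ± 0.47 (10 when adjusted over the list alone; camera adjusted p = 9.27e-13, or 0.0193 with an estimated correlation). Of 20 IL-17-response genes, 9 were lower (11 lower and 1 higher when adjusted over the list alone; adjusted p = 6.68e-07, or 0.0355 with an estimated correlation). Notch genes were higher in 2 of 10 cases, Notch3 at 1.77 ± 0.19 and Heyl at 2.74 ± 0.39 (4 when adjusted over the list alone; adjusted p = 0.000619, or 0.0355 with an estimated correlation). Mural markers were higher in 3 of 8 (4 when adjusted over the list alone; adjusted p = 0.000226, or 0.0355 with an estimated correlation). Sublining genes were higher in 6 of 15 cases and lower in 1, with Clec3b at 1.26 ± 0.11 (the same when adjusted over the list alone; adjusted p = 3.65e-05, or 0.224 with an estimated correlation). Lining genes were higher in 5 of 12 cases and lower in 1, with Timp3 at 1.40 ± 0.31 and Thbs4 at -0.97 ± 0.21 (8 and 1 when adjusted over the list alone; adjusted p = 0.000226, or 0.339 with an estimated correlation).

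Glycolysis genes were lower in 4 of 23 cases (9 when adjusted over the list alone; adjusted p = 0.000226, or 0.545 with an estimated correlation). Cytokine genes were lower in 5 of 22 with Ccl5 higher (7 lower and 2 higher when adjusted over the list alone; adjusted p = 0.00776, or 0.374 with an estimated correlation). Interferon genes were lower in 2 of 29 cases, Rsad2 at -1.80 ± 0.34 and Ifit3 at -1.49 ± 0.37, and higher in 1 (3 and 2 when adjusted over the list alone; adjusted p = 0.036, or 0.722 with an estimated correlation). Collagen genes were higher in 4 of 32 cases and lower in 3 (10 and 4 when adjusted over the list alone; adjusted p = 0.0206, or 0.516 with an estimated correlation). Checkpoint genes were higher in 3 of 15 (4 when adjusted over the list alone; adjusted p = 0.0487, or 0.347 with an estimated correlation). Cell-cycle genes were higher in 1 of 19 and lower in 1 (9 and 1 when adjusted over the list alone; adjusted p = 0.00569, or 0.545 with an estimated correlation). Cartilage and bone markers were higher in 3 of 10 cases and lower in 1 (4 and 1 when adjusted over the list alone; adjusted p = 0.0124, or 0.339 with an estimated correlation). Muscle markers were lower in 1 of 8 (2 when adjusted over the list alone; adjusted p = 0.036, or 0.545 with an estimated correlation). The test called 1090 genes, 652 higher and 438 lower. With a library term edgeR called 0, with 1028 at an unadjusted p under 0.05, and 10 of the lists passed, the myofibroblast list at 9.64e-10. The count was 473 without TNF-inhibited animal 2, and 682 and 495 without IL-17-inhibited animals 1 and 2. None of the 21 named genes passed with the library term, where Csf3 changed sign (0.90), and 16 always passed without each animal in turn. Lrrc15 (0.054), Timp3 (0.074) and Ctla2a (0.07) lost their call without TNF-inhibited animal 2, Ctla2a also without IL-17-inhibited animal 2, Ifit3 (0.071) without TNF-inhibited animals 2 or 3 or IL-17-inhibited animals 1 or 3, and Ccl5 (0.11) without any 1 animal, each with the highest adjusted p given.

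To ask whether the inhibitors changed the same genes, both were set against the shared untreated animals. There 93 genes were higher and 149 lower with both, and 13 were called in opposite directions. Across genes, which are not independent replicates, the log2 fold changes had a correlation of 0.43, where simulated unchanged groups against the same animals gave 0.482 to 0.545, so that it was not above what shared animals give. Their covariance was 0.0968 against a simulated 0.0381, a difference of 0.0587. The simulated value holds the shared animals but no difference between libraries. The 3 untreated animals are too few to split and were all of 1 library, so part of the excess may come from that library. The same limit holds for the arthritis change below. Of genes called in arthritic against healthy fibroblasts, 446 were called oppositely and 128 alike with IL-17 inhibition, and 141 and 196 with TNF inhibition. Of all these genes, 61.5% and 46.8% moved the opposite way (simulated 58.6% and 58.4%). The covariance of the arthritis and treatment changes was -0.103 for IL-17 inhibition (simulated -0.0388) and -0.0145 for TNF inhibition (simulated -0.0386). With FAP-sorted animals in place of the untreated ones on the arthritis axis, the correlations across genes were 0.0006 for IL-17 and 0.15 for TNF inhibition, with simulated means of -0.00214 and -0.00616.

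To see how far the treated animals stood from healthy ones, each treated group was also compared with the healthy group. Mmp3 was above healthy by 3.85 ± 0.21 with TNF inhibition (adjusted p = 7.0e-08) and by 2.71 ± 0.20 with IL-17 inhibition (adjusted p = 1.2e-06). The largest rises with TNF inhibition included the acute-phase gene Hp at 4.82 ± 0.40, Cxcl9 at 4.77 ± 0.64, Lcn2 at 4.59 ± 0.31 and Saa3 at 4.67 ± 0.43. Those with IL-17 inhibition included Il4i1 at 5.29 ± 0.54, Cd74 at 5.00 ± 0.70, Ccl5 at 4.93 ± 0.60 and H2-Q6 at 5.08 ± 0.43. Myoc, which encodes myocilin, was lower by a log2 change of -4.52 ± 0.25 and -3.61 ± 0.24 (n = 3 in each group, all adjusted p under 0.05). Myoc was also among the 10 leading genes of the cluster most often annotated Pi16+. Of 29 interferon-response genes, 27 were higher with TNF inhibition (27 when adjusted over the list alone; camera adjusted p = 9.88e-25, or 0.103 with an estimated correlation). With IL-17 inhibition, 23 were higher (24 higher and 1 lower when adjusted over the list alone; adjusted p = 4.03e-24, or 0.169 with an estimated correlation). Matrix-degradation genes were higher in 10 and lower in 2 of 12 cases with TNF inhibition (the same when adjusted over the list alone; adjusted p = 2.62e-07, or 0.0287 with an estimated correlation). They were higher in 8 and lower in 1 with IL-17 inhibition (8 and 2 when adjusted over the list alone; adjusted p = 4.34e-06, or 0.0358 with an estimated correlation). Cd200 had log2 changes of -0.15 ± 0.30 (adjusted p = 0.74) and -0.30 ± 0.30 (adjusted p = 0.47), and Dkk3 was higher by 0.62 ± 0.14 and 0.84 ± 0.14. The test called 5588 genes, 2812 higher and 2776 lower, for TNF inhibition and 5115, 2569 higher and 2546 lower, for IL-17 inhibition. With a library term the counts were 2788 and 1948, and Dkk3 with TNF inhibition lost its call (adjusted p = 0.095). The cytokine (13 and 9 of 22 genes), IL-17-response (12 and 9 of 20), complement (9 and 10 of 12) and glycolysis lists (19 and 15 of 23) were also higher and the sublining list (11 and 10 of 15) lower in both comparisons. The lining list (8 of 12) was lower with TNF inhibition, and the TNF and NF-kB feedback (9 of 18), myofibroblast (8 of 18) and cell cycle lists (3 of 19) were higher with IL-17 inhibition. Up to 4 genes of a list went the other way. Of these lists, only IL-17 response, sublining and complement with TNF inhibition and complement with IL-17 inhibition also passed with an estimated correlation, and the others had an adjusted p of 0.103 to 0.664. Neutrophil markers were higher (adjusted p = 0.0147, or 0.103 with an estimated correlation) and cartilage and bone markers lower with TNF inhibition (4 lower and 2 higher of 10, the same when adjusted over the list alone; adjusted p = 0.0103, or 0.256 with an estimated correlation), and muscle markers lower with IL-17 inhibition (adjusted p = 0.00936, or 0.506 with an estimated correlation).

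To describe the fibroblasts that the FAP and Pdpn gate selects, FAP-sorted arthritic animals (n = 5) were compared with untreated arthritic animals of the wider gate (n = 3). FAP-sorted fibroblasts held more collagen and matrix RNA and less cytokine RNA as lists, though neither passed with an estimated correlation (adjusted p of 0.352 and 0.21). Acan (chromosome 7, 79053483 to 79115099), the cartilage proteoglycan aggrecan, was higher by 3.23 ± 0.29 with 22.8 ± 7.73 against 2.49 ± 0.422 CPM (adjusted p = 7.9e-05). The collagen-modifying gene Cthrc1 was higher by 2.48 ± 0.24, Sparc by 1.35 ± 0.15 with 10700 ± 2170 against 4220 ± 198 CPM, C1qtnf3 by 2.5 ± 0.27 and the imprinted RNA H19 by 2.88 ± 0.47. Il6 was lower by a log2 change of -1.38 ± 0.07, the neutrophil attractant Cxcl2 by -1.38 ± 0.22, Ccl11 by -2.23 ± 0.19 and Inmt by -2.76 ± 0.45. Cd200 was lower (-0.82 ± 0.20, adjusted p = 0.0075) and Dkk3 higher (0.80 ± 0.12, adjusted p = 0.0006), while Mmp3 had -0.17 ± 0.07 (adjusted p = 0.069). Of 32 collagen and matrix genes, 22 were higher and 1 lower (28 and 2 when adjusted over the list alone; camera adjusted p = 2.01e-07, or 0.352 with an estimated correlation). Of 22 cytokine genes, 12 were lower and 1 higher (the same when adjusted over the list alone; adjusted p = 2.01e-07, or 0.21 with an estimated correlation). Of 18 TNF and NF-kB feedback genes, 11 were lower (11 when adjusted over the list alone; adjusted p = 0.000303, or 0.352 with an estimated correlation). Lining genes were lower in 9 of 12 cases and higher in 1 (the same when adjusted over the list alone; adjusted p = 0.00458, or 0.147 with an estimated correlation). Interferon genes were lower in 13 of 29 (13 when adjusted over the list alone; adjusted p = 0.00682, or 0.663 with an estimated correlation). Notch genes were lower in 3 of 8 (3 when adjusted over the list alone; adjusted p = 0.04, or 0.448 with an estimated correlation). The test called 5751 of 13418 genes, 2862 higher and 2889 lower, 784 of them by over 2-fold. Groups did not overlap for 41.9% of genes, where chance gives 3.57%.

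Markers of other cells differed as well. Muscle markers were lower in 8 of 8 cases, with Tnnt3 at -4.98 ± 0.21, or 1.46 ± 0.327 against 45.9 ± 13.1 CPM (8 when adjusted over the list alone; adjusted p = 8.68e-94, or 0.00164 with an estimated correlation). Neutrophil markers were higher in 6 of 6, with Ngp at 4.36 ± 0.41 (6 when adjusted over the list alone; adjusted p = 1.47e-12, or 0.0439 with an estimated correlation). Endothelial (4 of 7, adjusted p = 0.00266, or 0.11 with an estimated correlation), keratinocyte (2 of 3, adjusted p = 0.00441, or 0.113 with an estimated correlation) and erythroid markers (2 of 2, adjusted p = 0.0434, or 0.21 with an estimated correlation) were lower, with the same numbers when adjusted over the list alone. Cartilage and bone markers were higher in 3 and lower in 3 of 8 cases (the same when adjusted over the list alone; adjusted p = 0.653). Median deposited stress scores were 0.11 to 0.37 in FAP-sorted and 0.64 to 0.80 in untreated animals, and the median mitochondrial share was 2.98% to 3.35% against 2.29% to 2.36%. Mmp3+ fibroblasts made up 61.5% ± 9.93 of FAP-sorted fibroblasts, Il6+ 19.2% ± 5.46, Pi16+ 8.52% ± 2.59, Cd200+ 7.22% ± 2.67 and lining 3.58% ± 0.669. Against untreated animals, the Il6+, Pi16+ and lining shares differed with a two-sided exact permutation p of 0.0179 (adjusted p = 0.0298), the smallest that 56 splits can give, Mmp3+ with an exact p of 0.0357 (adjusted p = 0.0446) and Cd200+ with an exact p of 0.482. Without any 1 untreated animal, where fewer splits remain, the adjusted p of these shares was 0.0595 to 0.119. Without FAP-sorted animal 1 it was 0.0714 for the 4 classes, and without animals 4 or 5 the same for Pi16+ or Mmp3+. Ckm had 2 UMIs in the FAP-sorted animals together and 2493 in the untreated ones, a CPM ratio of 1540 with an exact 95% counting interval of 426 to 12700. The gate, the library and the Cell Ranger version in the file headers, 5.0.0 against 6.0.0, were the same split of the animals.

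Of the other cells of the wider gate, endothelial-like cells were compared between the arthritic groups. With IL-17 inhibition, Cd74 was higher by 3.68 ± 0.35 with 735 ± 331 against 55.7 ± 14.8 CPM (n = 3 each, adjusted p = 0.00016), H2-Ab1 by 3.72 ± 0.45, H2-Eb1 by 3.74 ± 0.44, H2-Aa by 3.57 ± 0.41 and H2-DMb1 by 3.39 ± 0.45. Clca3a2, Cxcl13, Igfbp3, Prnd and Nox4 were lower, with -2.80 ± 0.36, -2.92 ± 0.62, -2.07 ± 0.44, -1.69 ± 0.32 and -1.65 ± 0.40. With TNF inhibition, Cd74 was higher by 2.26 ± 0.35 (adjusted p = 0.0053), Cytl1 by 2.85 ± 0.43, Col8a1 by 2.96 ± 0.46 and Atp2a3 by 3.57 ± 0.59 (3.78 ± 0.57 with IL-17 inhibition). Prnd, Piezo2 and Nox4 were lower, with -2.78 ± 0.37, -2.45 ± 0.43 and -2.10 ± 0.43. A part of fibroblast RNA was not tested, though Cxcl13 also fell in fibroblasts and Igfbp3 and Col8a1 were leading genes of fibroblast-like clusters. The test called 223 of 8315 genes with IL-17 inhibition (169 higher, 54 lower) and 192 with TNF inhibition (139 higher, 53 lower). Without untreated animals 1, 2 and 3 the counts were 74, 47 and 99 for IL-17 and 74, 62 and 89 for TNF inhibition. They were 105 and 60 without IL-17-inhibited animals 1 and 2, and 94 and 118 without TNF-inhibited animals 1 and 3. With IL-17 inhibition Nox4 lost its call without any 1 animal, Igfbp3 without any 1 but IL-17-inhibited animal 1, Cxcl13 without untreated animal 2 or any 1 IL-17-inhibited animal and Prnd without animal 2 of either group, with adjusted p up to 0.17, 0.12, 0.14 and 0.094. With TNF inhibition, Nox4 (0.086) lost its call without any 1 untreated animal or TNF-inhibited animal 1 and Piezo2 (0.053) without untreated animal 2. With 9, 14 and 14 endothelial-like cells in healthy animals (minimum 20), no library term could be fitted.

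Mural-like cells, which carry pericyte and smooth muscle markers, reached 20 cells in 1 untreated, 2 healthy, 2 TNF-inhibited and 3 IL-17-inhibited animals, and the lone untreated animal was assumed to vary like the other groups. Against healthy animals, the class I gene H2-Q7 was higher by 4.92 ± 0.55 and Col14a1 by 4.83 ± 0.89, and the potassium channel gene Kcnk3, Id1 and Cck were lower, with -4.15 ± 0.91, -4.61 ± 1.06 and -3.86 ± 0.58 (117 of 5719 genes called). Against this 1 untreated animal, Csf3 was higher by 4.56 ± 0.52 and Pdpn lower by a log2 change of -3.37 ± 0.53 in TNF-inhibited animals (12 genes called). In IL-17-inhibited animals Mmp3, Lcn2, Cxcl14 and Pdpn were lower, with -3.97 ± 0.32, -4.00 ± 0.61, -3.93 ± 0.36 and -3.20 ± 0.46 (10 genes called). Fibroblast genes such as Pdpn, Col14a1 and Mmp3 were thus among those high in the single untreated animal, which had 22 cells, so that no difference in mural-like cells can be given to arthritis or an inhibitor. Col14a1 had 2 UMIs in the healthy animals, and Kcnk3 and Id1 had 2 and 3 in the untreated animal, so that the CPM ratios of 29.9, 19.2 and 26.9 had exact 95% counting intervals of 7.83 to 255, 5.04 to 163 and 8.95 to 132. The counts were 13 without healthy animals 2 or 3, 19 and 6 without TNF-inhibited animals 2 and 3, and 3 without IL-17-inhibited animals 1 or 2. In these fits Col14a1, Id1 and Kcnk3 lost their call against healthy animals (adjusted p up to 0.11, 0.22 and 0.18), as did Pdpn with TNF inhibition (0.069) and Pdpn and Lcn2 with IL-17 inhibition (0.093 and 0.15). Among all named and unnamed cell classes, endothelial-like cells made up 1.53% ± 0.613 of the cells of healthy and 3.77% ± 0.59 of those of untreated arthritic animals, keratinocyte-like cells 6.34% ± 3.86 and 0.736% ± 0.184, and mural-like cells 2.62% ± 1.54 and 0.847% ± 0.403. No class passed the two-sided exact permutation test within libraries, with an adjusted p of 0.0625 at best over 8 classes. With a filter of 1000 genes and 5% mitochondrial UMIs, the endothelial-like, lymphatic endothelial-like and keratinocyte-like shares passed at an adjusted p of 0.0417.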

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

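Chosen only after the result was seen were the comparison of levels within the Mmp3+ class, the comparisons of muscle, keratinocyte and neutrophil RNA between cell types and all splits of the animals.

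One value lay far from the others of its group. Ckm RNA stood at 0.0713 CPM in FAP-sorted animal 4 and at 0 in the other 4 FAP-sorted animals, a gap that rests on 2 UMIs. It was 1 of 25 values tested in this way, and chance flags about 1 in 20 groups.

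The TNF-inhibited and IL-17-inhibited animals differed in 1090 genes by the edgeR test of the difference itself. Among them were 13 named gene models called in opposite directions against untreated animals, lower with TNF inhibition and higher with IL-17 inhibition for 12 of the 13. Between the treatments, Tagln differed by 2.44 ± 0.30, Scg3 by 2.45 ± 0.24, Acta2 by 2.35 ± 0.20 and Il2rg by 2.45 ± 0.26 on the log2 scale (n = 3 each). Within the Il6+ class alone, Tagln had a difference of -0.03.

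Genes changed with treatment were weighed against a library difference and a changed mix of fibroblast classes. Levels within classes argue against a changed class mix as the whole cause, but a changed mix inside a class was not tested. Intervals resample genes, called in sums with these cells, and hold no spread between animals. In the median called gene, the Il6+ class showed 0.89 of the IL-17 change in all fibroblasts (95% bootstrap interval 0.87 to 0.92, 858 genes). Within the Mmp3+ class the ratios were 0.95 (0.93 to 0.98, 587 genes) for TNF and 1.03 (1.01 to 1.07) for IL-17 inhibition. The 0.79 (0.74 to 0.83) for TNF inhibition within the Il6+ class does not decide. Library and treatment cannot be told apart, as each treatment was 1 library bridged by 1 healthy animal. Between the healthy animals, the same genes differed by 0.41 (0.36 to 0.46) of the TNF change and 0.35 (0.31 to 0.38) of the IL-17 change, and 27 interferon genes by 0.37 (0.07 to 0.45) and 0.06 (-0.15 to 0.30), values between those set for and against the library or too wide to decide. Inhibitor effects thus stay untested beside the library, whose part may be large.

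Muscle and keratinocyte RNA in fibroblasts differed between libraries and may be free RNA shared within a well. The summed CPM of 8 muscle genes in the untreated, TNF-inhibited and IL-17-inhibited libraries was 341, 140 and 101 in the healthy fibroblasts, 238, 100 and 73.9 in the arthritic ones and 123, 104 and 82.5 in endothelial-like cells. For 7 keratinocyte genes it was 26.5, 54.8 and 77.0 in healthy fibroblasts, 16.4, 30.4 and 44.4 in arthritic ones and 12, 29.6 and 48.9 in endothelial-like cells, so that the order of the libraries was the same in cells that should lack these genes, with and without treatment. In the FAP-sorted library the sums were 4.02 and 10.7. For 10 neutrophil genes the sums were 20.3, 18.0 and 17.7, then 48.9, 34.5 and 29.3, and 34.5, 22.7 and 19.7, in the same order of cells and libraries, and 117 in the FAP-sorted library. Of these, S100a8 and S100a9 are also IL-17-response genes, and the source of their RNA was not tested. None of the muscle and keratinocyte genes is in another list, the CD45 gate does not remove muscle or skin cells, and no biological explanation was tested.

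Y-linked UMIs, not compared, were in 23.1% of 541 and 17.7% of 413 fibroblasts under the healthy hashtag of the TNF-inhibited and IL-17-inhibited libraries. In 8 arthritic animals with few such cells it was 2.34% to 4.87%. Arthritic cells given the healthy hashtag are argued against, since 38.9% of these cells (77 of 198, exact 95% interval 32.1 to 46.1) were Pi16+. Xist-only cells were 45.3% Pi16+ (286 of 632, 41.3 to 49.2), as both sexes under 1 healthy hashtag would give. Each sample would then hold over 1 animal.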

How the results depend on the processing

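Chosen only after the data were seen were the tests on cells with the same HTODemux call, on all 7 annotated classes, within the Il6+ class alone, with a sex term, with the healthy animal of the untreated library only, the replicate block for gene lists and all splits of the animals.

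Counts of called genes lay within 1.5 times the value reported in 130 of 198 alternative fits. DESeq2 size factors, a filter of 10 CPM, the sex term, own fibroblast-like clusters, all 7 classes and cells with the same HTODemux call moved no count by more. Of 3706 values of named genes, 3166 kept their direction and their side of the threshold, 504 kept the direction but no longer passed, 15 newly passed and 21 changed sign. Of 621 values of single gene lists 483 kept both, 92 no longer passed, 40 newly passed and 6 that had passed changed direction. Of 200 class shares 150 kept both, 43 no longer passed, 1 newly passed and 6 changed sign.

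The library term ended all calls between the arthritic groups. From 797, 1212 and 1090 genes, edgeR called 0 for TNF inhibition, 0 for IL-17 inhibition and 0 between the inhibitors, with 799, 1107 and 1028 at an unadjusted p under 0.05, where DESeq2 without the term called 1448, 1671 and 1443. The counts against healthy animals fell from 4116 to 2317 for untreated, from 5588 to 2788 for TNF-inhibited and from 5115 to 1948 for IL-17-inhibited animals. This fit rests each effect on 1 healthy animal per library. At the preset correlation, gene lists passing went from 9 to 4 for TNF and from 11 to 6 for IL-17 inhibition. Among these, muscle (adjusted p = 0.923) and keratinocyte lists (0.923) changed direction for TNF inhibition, erythroid (0.636), cartilage and bone (0.483) and keratinocyte lists (0.345) for IL-17 inhibition, and cartilage and bone (0.557) between the inhibitors. Genes that changed sign were Mt3 (-0.70), Adamts4 (0.17) and Ckm (0.39) for TNF inhibition, Krt14 (-0.04), Ccl5 (-0.52), Tagln (-0.06), Mmp9 (-0.50), Ckm (0.22) and Atp2a1 (0.38) for IL-17 inhibition, and Csf3 (0.90) between the inhibitors. Genes called with both inhibitors went from 93 and 149 to 0 and 0, and the correlation of the responses from 0.432 to 0.346. The correlation with the arthritis change went from -0.0325 to -0.311 for TNF and from -0.228 to -0.291 for IL-17 inhibition.

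Single classes held fewer cells. Within the Mmp3+ class, 872 genes passed in untreated animals against healthy ones, 777 and 665 in TNF-inhibited and IL-17-inhibited animals against healthy ones, and 297 with TNF inhibition. The healthy animals held only 16, 17 and 24 Mmp3+ cells and were fitted all 3, without the minimum of 20. Within the Il6+ class the same counts were 790, 1302, 1133 and 29, with 256 for IL-17 inhibition, 90 between the inhibitors and 2522 for the FAP sort, from 5751. Against healthy animals, Engase (6.68), Dpp4 (6.13) and Slc16a3 (-0.37) changed sign in the Mmp3+ class and Mmp12 (-0.55), Cd55 (0.18) and Dpp4 (0.30) in the Il6+ class, as did Dkk3 (-0.11) with TNF inhibition in the Mmp3+ class. Tagln (0.26) with TNF inhibition, Mmp3 (0.09) with IL-17 inhibition, and Tagln (-0.03) and Thbs4 (0.06) between the inhibitors changed sign in the Il6+ class. None of these passed there, those of the Mmp3+ class rest on these few healthy cells, and the cause was not tested. Genes called with both inhibitors were 12 and 4 in the Il6+ class, the correlation of the responses was 0.521 and that with the arthritis change for TNF inhibition -0.100. With the same HTODemux call these correlations were 0.411 and -0.00923, and -0.205 for IL-17 inhibition. Against the healthy animal of the untreated library only, with 1 animal in that group and the spread taken from the others, 2259 genes passed.

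With only the 2 groups compared, 2001 genes passed for IL-17 inhibition and 495 between the inhibitors, and in mural-like cells 465, 58 and 28, from 117 against healthy animals, 12 with TNF and 10 with IL-17 inhibition. The cause was not tested. With cells drawn to equal numbers, and so fewer, 468, 592 and 588 fibroblast genes passed for TNF inhibition, IL-17 inhibition and between them, 30 and 23 endothelial-like genes, from 192 and 223, and 66 mural-like genes against healthy animals. Without a low-count filter, which tests more genes, 506 and 569 endothelial-like and 308, 64 and 77 mural-like genes passed. DESeq2 called 3 and 3 mural-like genes with the inhibitors, and the cause was not tested. With the strict hashtag rule, and fewer cells, 80 endothelial-like genes passed for IL-17 inhibition.

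With each animal left out in turn, the counts were 105 to 781 for TNF inhibition, 326 to 754 for IL-17 inhibition and 473 to 1092 between them, 62 to 159 and 47 to 176 in endothelial-like cells, and 13, 6 to 19 and 3 to 12 in mural-like cells. Healthy minus arthritic shares ran from -41.9 to -34.5 percentage points for Mmp3+, 41.0 to 42.8 for Pi16+, -4.07 to 4.00 for Il6+ and -2.73 to 0.918 for Cd200+ fibroblasts. Across the 3 arthritic groups, the F statistic of Pi16+ ran from 4.17 to 84.4. FAP-sorted minus untreated shares ran from -2.79 to -2.31 for lining, 19.7 to 25.2 for Mmp3+, -31.3 to -26.9 for Il6+, 6.65 to 8.16 for Pi16+ fibroblasts and -0.232 to 0.096 for adipocyte-like cells. Of the 8 cell classes, 0 to 7 passed there by the exact test, 0 without any 1 untreated animal, where too few splits remain.

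The healthy minus arthritic Il6+ share was 1.31 points with the same HTODemux call. With the strict hashtag rule, the FAP-sorted difference was -2.04 for lining (adjusted p = 0.357) and -0.414 for Cd200+ fibroblasts, and the healthy minus arthritic share -0.719 for keratinocyte-like and -0.106 for Schwann-like cells. These rest on fewer cells. With 1000 genes and 5% mitochondrial UMIs, 3 cell classes passed between healthy and arthritic animals, from 0. With an estimated correlation, camera called 4 lists in untreated against healthy animals, 0 for TNF inhibition, 0 for IL-17 inhibition, 4 between the inhibitors, 4 and 2 for TNF-inhibited and IL-17-inhibited against healthy animals and 2 for the FAP sort, from 11, 9, 11, 14, 10, 11 and 11. Fry, which does not compare a list with other genes, called 6 between the inhibitors, 17 and 17 against healthy animals and 18 for the FAP sort.

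Animals with the same hashtag number in different libraries share only a number. Over 7342 genes, the correlations of 9 same-number pairs ran from -0.34 to 0.30, with 5 over 0.1, and 3 of 9 animals correlated best with their own number. With the number as a replicate block, 730, 978 and 859 fibroblast genes passed for TNF inhibition, IL-17 inhibition and between them, 187 and 164 endothelial-like and 6 and 9 mural-like genes, and 9, 12 and 16 gene lists.

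The 10 splits of 6 animals are too few for a share under 0.05. The real split, the only 1 of the 10 with as many genes each time, gave 4116 fibroblast genes for untreated against healthy animals, where the highest other split gave 0, and 797 for TNF inhibition (highest other 1), 1212 for IL-17 inhibition (0), 1090 between them (1), 5588 for TNF-inhibited (0) and 5115 for IL-17-inhibited against healthy animals (0). For endothelial-like cells it gave 192 and 223, and the highest other split 0 and 0. For the FAP sort, only the real split of 56 gave as many as 5751, with 11 as the highest other. The other splits mix sorted and unsorted animals, which widens the spread within their groups, so their low counts cannot exclude chance. The sort and the library cannot be told apart by these splits.

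No value was obtained for the strict hashtag rule in fibroblast comparisons with healthy animals, which had 18, 3 and 2 such cells, or in mural-like cells. The library term could not be fitted in endothelial-like and mural-like cells, nor the block against healthy animals or for the FAP sort. Endothelial-like cells of healthy animals numbered 9, 14 and 14 and were not tested, and the lone untreated animal with mural-like cells could not be left out. Depth limits these classes through the minimum of 20 cells. Of genes changed 1.5-fold, 17.9% were recovered from simulated fibroblasts of the 12 animals, 47.8% of the 8 animals and 7.5% from simulated endothelial-like cells, and depth was not varied there.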

Other observations

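The genes, classes and levels given here were chosen after their values were seen, and none was tested unless a test is named.

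MHC class II RNA was followed into cells outside the comparisons. In keratinocyte-like cells, Cd74 averaged 3.66 ± 1.57 CPM in healthy, 27.0 ± 46.8 in untreated, 137 ± 49.5 in TNF-inhibited and 413 ± 285 in IL-17-inhibited animals (n = 3 each), and H2-Ab1 averaged 1.14 ± 0.64, 2.84 ± 4.92, 32.2 ± 15.8 and 124 ± 92.4 CPM. These cells numbered 19, 81 and 53 in healthy, 10, 17 and 15 in untreated, 12, 40 and 13 in TNF-inhibited and 36, 71 and 24 in IL-17-inhibited animals, so that 6 of the 12 animals lay under the minimum of 20. In mural-like cells Cd74 stood at 5.95 (n = 2), 3.02 (n = 1), 7.07 (n = 2) and 7.35 ± 6.71 CPM (n = 3). In endothelial-like cells Ciita, which encodes the activator of class II genes, averaged 0.267 ± 0.463 in untreated, 1.81 ± 1.25 in TNF-inhibited and 8.76 ± 0.172 CPM in IL-17-inhibited animals, and the leukocyte gene Ptprc averaged 0.267 ± 0.463, 0 and 0. In fibroblasts Ciita averaged 0.0608 ± 0.0807, 0.0381 ± 0.0661 and 0.264 ± 0.219 CPM. On the TMM scale, fibroblast Cd74 stood at 2.61 CPM in the healthy animal of the IL-17-inhibited library and at 19.7, 82.8 and 56 CPM in its treated animals.

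Levels within single fibroblast classes are given for untreated, TNF-inhibited and IL-17-inhibited animals in this order (n = 3 each). In the Mmp3+ class, Saa3 averaged 66600 ± 10900, 60700 ± 11800 and 23600 ± 5510 CPM, Lcn2 7230 ± 916, 9650 ± 1070 and 2090 ± 755 CPM, and Acta2 39.1 ± 9.35, 9.95 ± 1.59 and 69.7 ± 6.27 CPM. In the lining class, Saa3 averaged 51800 ± 9360, 64100 ± 21900 and 13100 ± 7920 CPM. In the Il6+ class, Saa3 averaged 4930 ± 1070, 5920 ± 1310 and 3510 ± 1130 CPM and Mmp3 2910 ± 366, 3230 ± 407 and 3060 ± 1380 CPM. In the Cd200+ class, Cxcl10 averaged 876 ± 140, 3590 ± 2410 and 2280 ± 277 CPM.

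Clusters not compared had these shares of all cells in healthy, untreated, TNF-inhibited, IL-17-inhibited and FAP-sorted animals. Tenocyte-like cells made up 11.3% ± 1.28, 9.49% ± 2.62, 5.57% ± 0.827, 10.1% ± 2.1 and 8.74% ± 3.48. Osteoblast-like cells (most often annotated Mmp3+) were 3.71% ± 1.86, 5.38% ± 1.82, 7.93% ± 0.788, 13.1% ± 0.669 and 8.37% ± 1.46. The unnamed cluster made up 0.943% ± 0.613, 0.283% ± 0.194, 1.6% ± 0.274, 0.996% ± 0.199 and 1.04% ± 0.308.

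The FAP-sorted library also differed in its other cells. Endothelial-like cells made up 0.0461% ± 0.0427 of its cells (n = 5) against 3.77% ± 0.59 in untreated animals (n = 3), mural-like cells 0.0591% ± 0.0671 against 0.847% ± 0.403, and neutrophil-like cells 0.826% ± 0.248 against 0.253% ± 0.219. In the planned two-sided exact permutation tests, 7 of 8 classes had p = 0.0179, the smallest that 56 splits can give (adjusted p = 0.0204), and adipocyte-like cells had an exact p of 0.518.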
